A study of Acipenser sinensis with 6 samples.

How the data were processed

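RNA of palate tissue was extracted with Trizol from 3 cleft and 3 noncleft palate samples and made into Illumina libraries, per the labels' protocols. The submitters' processing notes name cutadapt, RSEM and DESeq, with no versions. The form of the contig IDs is that of the Trinity assembler. The assembly settings, the aligner used within RSEM and the libraries that entered the assembly are not given in the sources used here, nor is whether strand was kept. The authors deposited, per the file headers, an expected count and an FPKM value per contig for each library, and the contig length. Expected counts are RSEM's estimates, which divide reads that map to several contigs between them, so they need not be whole. FPKM as deposited by the authors is the count scaled to library size and to contig length less about the mean fragment length. A polyploid fish's assembly holds near-identical contigs from isoforms, gene copies and alleles, and reads can be split between them, so the level of a single contig is less certain than that of its family.

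Groups were taken from the sample titles and the series' design. Of the contig IDs, 0 matched the gene IDs, locus tags or symbols of the reference gene table given for this species, and no sequences were given to match. The 35 gene lists fixed before the data were examined, for pathways and for markers of other tissues a dissected palate could hold, were therefore not tested, and no tissue makeup is reported.

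Expected counts were rounded to whole numbers. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the legacy option on, which is this version's default, and the filterByExpr filter, which left 76254 contigs, with group as the only term and Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM, counts scaled to library size, after TMM scaling, with TMM factors of 0.846, 1.18 and 1.01 in the cleft and 0.913, 1.02 and 1.07 in the noncleft palate libraries. The square root of edgeR's common dispersion, the coefficient of variation between replicates, was 0.547, and 0.367 without cleft palate library 1. The rule for naming contigs without gene names was the 2 with the smallest adjusted p in each direction among those past the threshold, with a log2 fold change of at least 1 in size and groups that do not overlap. No contig passed the threshold, so the 4 named were chosen by the same rule without it, after their values were seen.

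The depth was 12624838 to 16318126 counts per library. On simulated counts with the real means, library sizes and dispersions and 200 changed contigs, for the comparison of cleft with noncleft palate over 70009 contigs, edgeR recovered 89 of 100 contigs changed 32-fold and 0 of 100 changed 4-fold, with 5 false calls. DESeq2 (1.42.0) recovered 98 of 100 and 45 of 100, with 129 false calls. With dispersions estimated without cleft palate library 1, over 70872 contigs, edgeR recovered 98 of 100 and 47 of 100, with 30 false calls. With no contig changed, over 70012 contigs, edgeR made 0 and DESeq2 79 false calls.

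The alternatives fixed before the data were examined were DESeq2, RLE size factors, no low-count filter, a mean count of at least 50, an adjusted p of 0.01, leaving out each library, the replicate number as a block, and limma (3.58.1) on log2(FPKM + 1) over contigs with a mean FPKM of at least 1. Added later were limma on log2(FPKM + 0.1), counts summed per contig family, edgeR with robust dispersion and with the legacy option off, limma's voom with sample quality weights, DESeq2 without cleft palate library 1, and the settings for contigs at 0. Similarity used Spearman correlation of log2(CPM + 0.5) over the contigs that passed filterByExpr, with Pearson correlation and a mean count of at least 50 as alternatives, and a mean count of at least 10 added later. Differences of single libraries from the median of the others, and sets of contigs defined by cleft palate library 1, used contigs with a mean count of at least 10. Equal depth was made by drawing each library down to the smallest total. The mean fragment length was taken from the straight line of count divided by FPKM against contig length, over contigs longer than 800 nt. No pair of libraries was a duplicate, since the chi-square per contig between libraries was 8.1 or more, where sampling noise alone gives 1. The gap test for a single outlying library was not run, since groups of 3 are too small for it. The quality weights that limma's voom estimated were 0.153, 2.48 and 0.928 in the cleft and 1.74, 1.92 and 0.85 in the noncleft palate libraries. DESeq2 gave no adjusted p for 150 contigs, and for 3 without cleft palate library 1, which were not counted as called.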

Results

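Palate tissue of the Chinese sturgeon (Acipenser sinensis) was profiled by RNA sequencing in 3 cleft palate samples and 3 noncleft palate samples. All 6 were taken at an age of 4 months, from a population labelled artificial. Expression was given for 808612 contigs, which are transcript sequences put together from the reads, in 711668 contig families that the assembler's IDs treat as 1 gene each. The contigs were 201 to 18720 nt long, with a median of 346 nt. The cleft palate libraries held 16197525, 14080918 and 16016042 estimated counts, and the noncleft palate libraries held 12624838, 16318126 and 13983201. The labels do not say that the samples came from separate fish, so the p-values measure only the spread between these samples, which may be technical. The files pair no contig with a gene name or a genome position, so contigs are described by ID, length, family and level, and chromosome, exon and UTR are not given.

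The comparison of cleft with noncleft palate asks which transcripts differ with the malformation. The contig with the smallest p-value was TRINITY_DN286927_c2_g3_i2, of 1587 nt. It stood at 0.28 ± 0.10 CPM (counts scaled to library size; SD, n = 3) in the cleft palate and at 19.3 ± 1.70 CPM (SD, n = 3) in the noncleft palate. TRINITY_DN270533_c4_g2_i1, of 4877 nt, stood at 0.41 ± 0.13 CPM in the cleft and 11.5 ± 2.78 CPM in the noncleft palate. In the opposite direction, TRINITY_DN271992_c3_g1_i3, of 1470 nt, stood at 37.7 ± 15.4 CPM in the cleft and 6.02 ± 0.18 CPM in the noncleft palate, and TRINITY_DN295345_c4_g12_i1, of 336 nt, at 5.41 ± 2.09 and 0.54 ± 0.17 CPM. None of the 76254 contigs tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where 3511 had an unadjusted p under 0.05. DESeq2 called 109 of the same contigs, and limma on log2(FPKM + 1) called 44 of the 218232 contigs that it tested. Without the low-count filter edgeR tested 594378 contigs and called 758, of which 535 were higher and 223 lower in the cleft palate. With the filter kept and the legacy option off, edgeR called 1. Of the 758, 381 were contigs that pass the filter, and 143 were at 0 in 4 or more libraries. In 335 of them all counts of one group lay above all of the other.

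The size of the difference at TRINITY_DN286927_c2_g3_i2 was a log2 fold change of -6.09 ± 0.42 (SE), with an edgeR adjusted p of 0.0523. Its counts were 5, 3 and 4 in the cleft palate libraries and 203, 294 and 303 in the noncleft palate libraries. The family of this contig holds 1 other contig, and the family as a whole averaged 10 counts per cleft library and 270.3 per noncleft library. In edgeR fits with 1 library left out, the contig passed the threshold without cleft palate library 1, with a log2 fold change of -6.38 and an adjusted p of 0.016. It did not pass without any of the other 5, where edgeR adjusted p-values were 0.52 to 0.856. It passed in edgeR when contigs under a mean count of 50 were left out, with an adjusted p of 0.0471, and with the legacy option off, with an adjusted p of 0.0361. Over all fits of edgeR, DESeq2 and limma its adjusted p ranged from 2.88e-22 to 0.884. The log2 fold change of TRINITY_DN270533_c4_g2_i1 was -4.79 ± 0.45 (SE), with an edgeR adjusted p of 0.273 and counts of 6, 8 and 4 against 101, 175 and 207. TRINITY_DN271992_c3_g1_i3 differed by 2.65 ± 0.38 on the log2 scale, with counts of 321, 527 and 846 against 66, 99 and 84. TRINITY_DN295345_c4_g12_i1 differed by 3.29 ± 0.50, with counts of 101, 65 and 66 against 4, 11 and 8. Both had an edgeR adjusted p of 0.869. No other contig shares a family with these last 3. Without the low-count filter, edgeR called all 4 contigs, with adjusted p-values of 7.47e-16, 6.67e-10, 0.000497 and 0.00399 in the order given. That fit also called 391 to 802 contigs when the libraries were grouped otherwise, 3 against 3. A small adjusted p from it is therefore not by itself evidence of a difference between the groups. The 4 contigs were chosen among those whose groups do not overlap. That choice by itself fixes the two-sided exact permutation p of each at 0.1, the smallest that 3 against 3 libraries can give. In effect it also fixes their direction in the other fits, so a kept direction is not evidence of robustness.

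**Figure D1:**
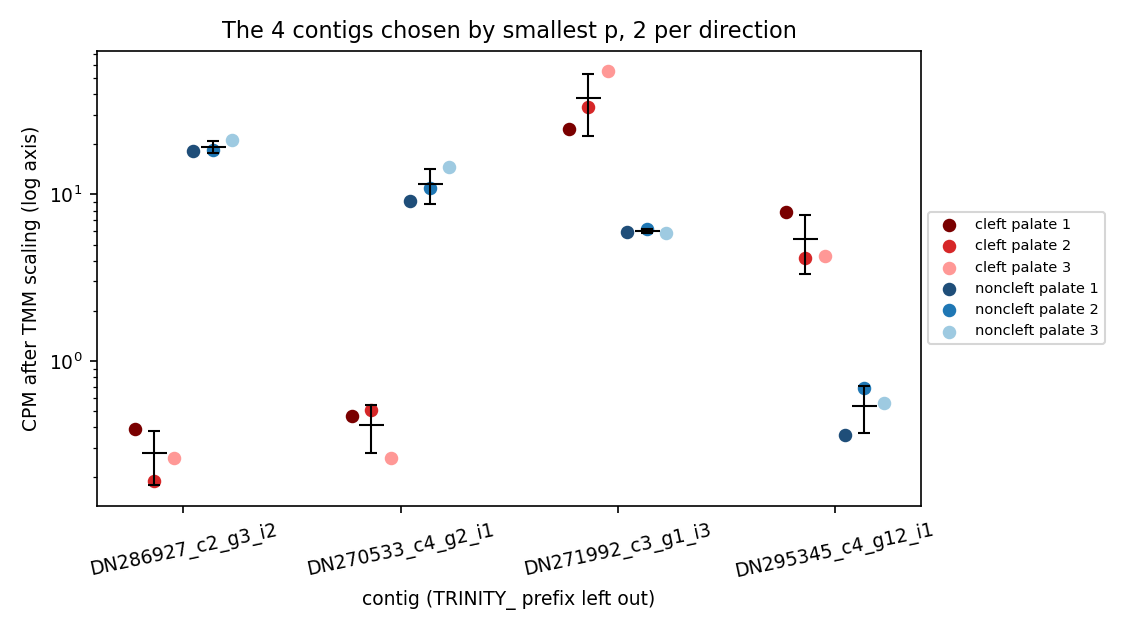
Level of 4 contigs in each library, in CPM after TMM scaling on a log axis; coloured points are libraries, black bars are group means with the SD (n = 3). All cleft palate libraries lie below all noncleft ones for the left pair (0.28 against 19.3 CPM and 0.41 against 11.5 CPM) and above them for the right pair (37.7 against 6.02 CPM and 5.41 against 0.54 CPM).

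Of the 3511 contigs with an unadjusted edgeR p under 0.05, 2483 were higher and 1028 lower in the cleft palate. They were 4.6% of those tested, below the share of 0.05 that this threshold passes in theory when no contig differs. Other groupings of these libraries, 3 against 3, gave 1286 to 2862 such contigs, so 0.05 need not be the share without a difference here. These groupings are too few for a test. Without cleft palate library 1 there were 4513 contigs at this threshold, 5.45% of the 82784 then tested, of which 2441 were higher and 2072 lower. Their number was 7800 without cleft palate library 3, 9.32% of 83647 tested, and 2088 without noncleft palate library 1, 2.31% of 90261. All 3 libraries of one group lay above all 3 of the other in 9911 contigs, 13% of those tested, where chance gives 10% on average. Of these, 4923 were higher and 4988 lower in the cleft palate. The share was not computed for other groupings of the libraries, so 13% against 10% is not a test of the groups. DESeq2's Wald test on the same contigs called 109, with 54 higher and 55 lower in the cleft palate, including the 4 contigs named above. Its calls were moderately expressed contigs with large differences, with a median mean count of 40.3 and a median absolute log2 fold change of 3.96. In 23 of them every cleft palate library was at 0, and in 4 every noncleft palate library was. Without cleft palate library 1 DESeq2 called 217 contigs, 94 higher and 123 lower, of which 74 were among the 109. In simulated counts with no contig changed, DESeq2 called 79 contigs and edgeR called 0. That was a single draw with the same dispersion in every library, so it holds no outlying library and is not a false-call rate for these data.

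Contigs were also grouped by length, with no test of the difference between classes. The 1570 tested contigs under 300 nt had a median log2 fold change of 0.22 in the cleft palate (quartiles -0.29 and 0.84), and 109 of the 130 with an unadjusted edgeR p under 0.05 were higher there. The 15829 contigs of 2000 nt or longer had a median of -0.12 (quartiles -0.49 and 0.29), with 295 higher and 292 lower. Without cleft palate library 1 these medians were 0.07 and -0.05, and the contigs with an unadjusted edgeR p under 0.05 were 47 higher and 35 lower in the short class and 617 higher and 583 lower in the long class. With each of the other libraries left out, 53 to 253 of the short contigs were higher and 8 to 62 lower. That library had 11.2% of its counts on contigs under 500 nt, against 7.98% and 6.47% in the other cleft palate libraries and 6.01%, 6.78% and 6.63% in the noncleft ones. The mean fragment length that its deposited counts and FPKM imply was 301 nt, against 306 and 326 nt in the other cleft palate libraries and 327, 321 and 323 nt in the noncleft ones.

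**Figure D2:**
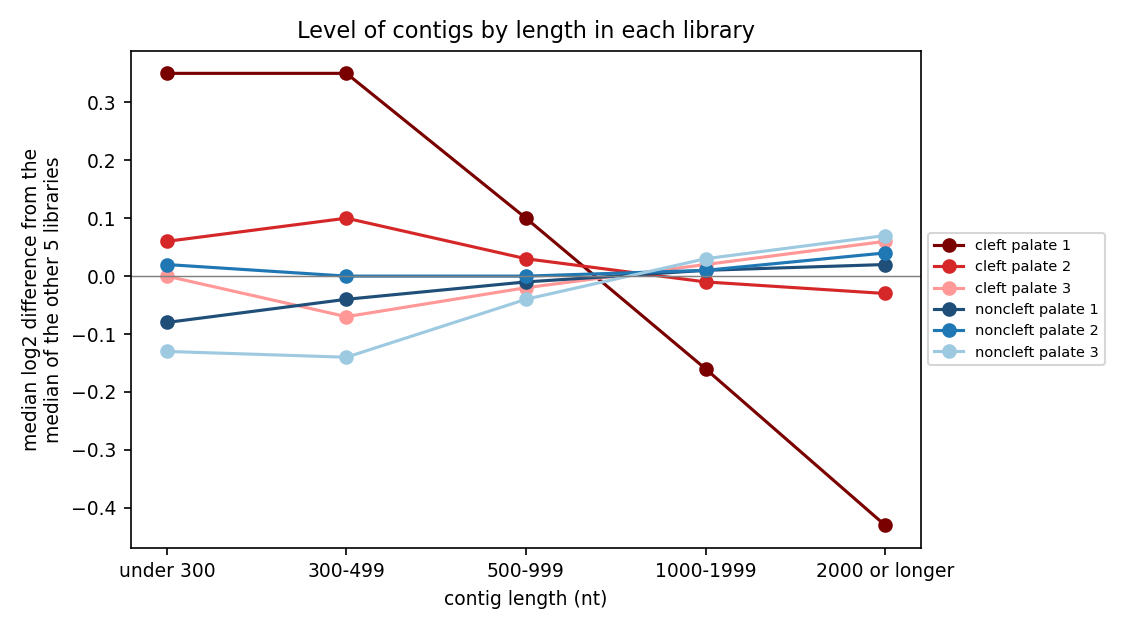
Median difference of contigs with a mean of at least 10 counts, by length class (x axis, nt), in each library from the median of the other 5 libraries, on the log2 scale (y axis). Cleft palate library 1 runs from 0.35 for the shortest class to -0.43 for the longest, while the other libraries stay between -0.14 and 0.10.

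The most abundant transcripts were described by the 10 contigs with the highest mean level in the noncleft palate. The first, of 2863 nt, made up 35574 ± 11918 CPM (SD, n = 3) in the noncleft palate, and stood at 609.1, 16426 and 42010 CPM in cleft palate libraries 1, 2 and 3. The second, of 4226 nt, stood at 24623 ± 4085 CPM in the noncleft palate and at 206.8, 8357 and 19852 CPM in the cleft palate libraries. Cleft palate library 1 lay more than 10-fold below the noncleft mean in 4 of the 10 contigs, by factors of 38.1 to 119.1. It lay above every noncleft library in 3 others, led by a contig of 2758 nt at 74792 CPM against 13929 ± 2796 CPM. Cleft palate libraries 1, 2 and 3 lay below every noncleft library in 7, 9 and 4 of the 10 contigs. The contigs of rank 9 and 10 belong to the same family, so these counts are not over separate genes. Choosing contigs by their noncleft level by itself favours lower values in the cleft palate, so the direction of these contigs is not a comparison of the groups. None of the 10 passed the test, with edgeR adjusted p-values of 0.869 to 0.927.

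**Figure D3:**
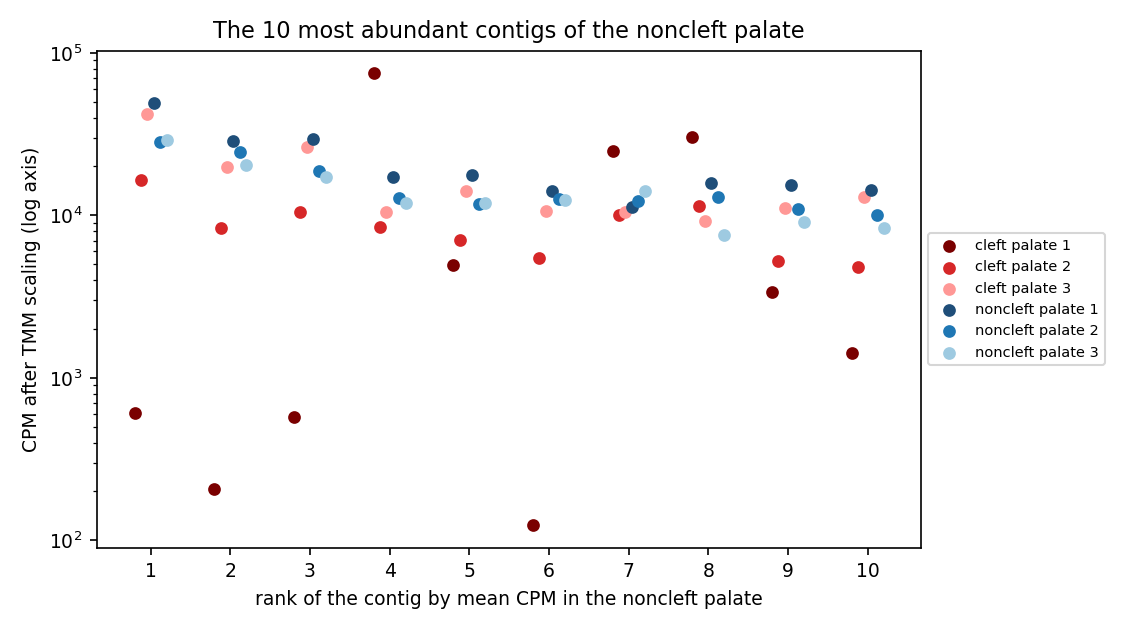
Level of the 10 contigs with the highest mean in the noncleft palate (x axis, by rank) in each library, in CPM after TMM scaling on a log axis; each point is 1 library. For the contig of rank 2, cleft palate library 1 lies at 206.8 CPM against a noncleft mean of 24623 CPM.

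Contigs absent from a whole group were also counted. At 0 counts in all 3 cleft palate libraries and at least 20 counts in every noncleft library were 9 contigs of 302 to 7224 nt, and none showed the reverse. The 9 contigs belong to 8 families. In 7 of these the family's other contigs had counts in every cleft palate library. The remaining family is a single contig of 1293 nt with 60, 73 and 132 counts in the noncleft libraries, and the floor of 3 counts over the cleft palate libraries makes it at least 95-fold lower there. That floor covers counting error only. With any 1 library left out, 20 to 36 contigs were at 0 in the remaining libraries of one group and at 20 counts or more in those of the other.

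The libraries were then compared as wholes, over the 76254 contigs tested. Cleft palate library 1 stood apart, with Spearman correlations of 0.535 to 0.656 with the other libraries, while these correlated with each other at 0.817 to 0.870. The first principal component held 60.4% of the variance and separated this library, at 0.90, from the others, at -0.28 to -0.07. Cleft palate libraries 2 and 3 correlated at 0.857. The mean correlation was 0.769 within groups and 0.754 between groups, a difference of 0.015 with a one-sided exact p of 0.1 over the 10 splits of the libraries, the smallest they allow. The highest other split gave 0.014, and with Pearson correlation the difference was 0.012 with a one-sided exact p of 0.2. Over contigs with a mean count of at least 50 it was 0.027 with a one-sided exact p of 0.1. The correlation within the cleft palate, 0.699, lay below that between groups, and the correlation within the noncleft palate, 0.839, lay above it. Without cleft palate library 1, 2 or 3 the difference was 0.003, 0.062 or 0.084, and it turned negative without noncleft palate library 1, 2 or 3, at -0.021, -0.015 and -0.025.

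**Figure D4:**
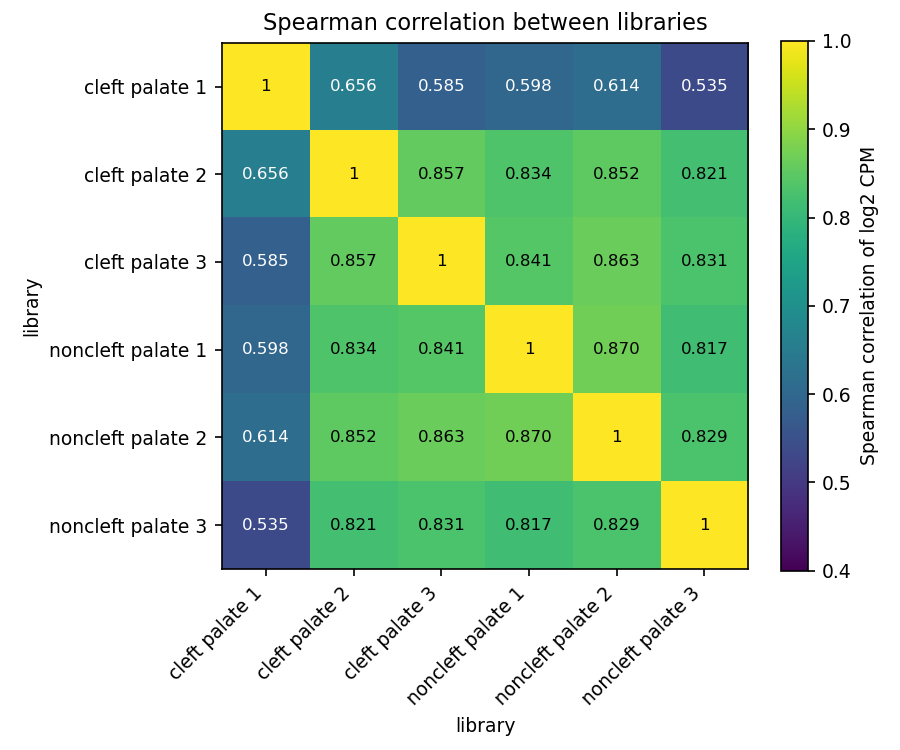
Spearman correlation of log2 CPM between each pair of libraries over 76254 contigs; rows and columns are libraries and the colour gives the correlation. The row of cleft palate library 1 holds 0.535 to 0.656, and all other pairs lie between 0.817 and 0.870.

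The number of contigs with at least 1 count was 296737 ± 17950 (SD, n = 3) in the cleft and 288164 ± 37808 (SD, n = 3) in the noncleft palate, a difference within the spread of the libraries (two-sided exact permutation p = 1). At equal depth it was 280812 ± 19112 and 277038 ± 29312 (two-sided exact permutation p = 1). At 10 or more counts it was 78817 ± 902 and 73675 ± 8677 (two-sided exact permutation p = 0.5). Noncleft palate library 1, the shallowest, had the fewest contigs with a count, 244521, and without it the cleft palate had fewer contigs than the noncleft, a difference of -13248. At equal depth this library still had the fewest, against 260183 to 301432 in the other libraries.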

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

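Chosen after the data were seen were limma on log2(FPKM + 0.1), sums per family, robust edgeR, edgeR with the legacy option off, voom with quality weights, DESeq2 without cleft palate library 1, similarity over contigs with a mean count of at least 10, and all settings for contigs at 0. DESeq2, the unfiltered edgeR fit and limma on FPKM moved the edgeR count of 0 called contigs, and in each of these the count was the same with at least a doubling or halving. The count was 109 with DESeq2, 758 without the low-count filter, 44 with limma on log2(FPKM + 1), 55 on log2(FPKM + 0.1), 1 at a mean count of at least 50 and 1 with the legacy option off. It was 0 to 1 when each library was left out in turn, the 1 being TRINITY_DN286927_c2_g3_i2 without cleft palate library 1. DESeq2 without that library called 217 contigs, 208 of them with at least a doubling or halving, and 74 of these 217 were among the 109. Of the 44 limma calls, 1 was among the 109, but the contigs tested also differed, 218232 with limma against 76254 with DESeq2. The cause of these differences was not tested, except that DESeq2 made 79 calls in simulated counts with no change. The stricter threshold adds nothing to a count of 0. The count stayed at 0 with RLE size factors, sums per family, robust edgeR, voom with quality weights (6891 contigs at an unadjusted p under 0.05) and the replicate block (0 called, 2261 at an unadjusted p under 0.05). The equal numbers are not stated to pair the libraries. Deviations of same-numbered libraries from their group means correlated at 0.06, -0.095 and 0.089, and not every library correlated best with its own number. Each mean rests on only 3 libraries, so this check cannot exclude pairing. The 4 named contigs kept direction where tested, as their choice fixes. The difference in contigs detected, 8573 more in the cleft palate, ranged from -13248 to 19959 when each library was left out, the lowest without noncleft palate library 1. The within-group less between-group correlation ranged from -0.025 to 0.084, being negative (-0.021, -0.015 and -0.025) without noncleft libraries 1, 2 and 3. The 9 contigs at 0 in one group became 24 at a minimum of 10 counts, 1 at 50, 1 when summed per family and 20 to 36 with 1 library left out, since fewer libraries must be at 0. Sums per gene name and the settings of the gene lists were not run, since contigs carry no names. At this depth and spread edgeR recovered 0 of 100 simulated changes of 4-fold. With dispersions estimated without cleft palate library 1 it recovered 47 of 100. These simulations, and that with no change, drew 3 against 3 libraries with the same dispersion in every library. None of them holds a single outlying library. Dispersions without any other library were not simulated, so whether the gain is particular to this library was not tested.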

Other observations

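The tests of depth, of a tissue part and of divided reads, and the counts of splits other than that for edgeR without the low-count filter, were chosen or worded after the result was seen. The sets of contigs below were also chosen after the data were seen. In cleft palate library 1, 8269 contigs stood 8-fold or more below the mean of the other 5 libraries. These contigs made up 26.6%, 23.0% and 23.5% of the counts in the noncleft palate libraries, 15.3% and 25% in cleft palate libraries 2 and 3, and 0.62% in cleft palate library 1. The selection itself makes the share in this library small. The same selection made for each of the other libraries gave 1204 to 2337 contigs, which made up at most 3.12% of the counts of any library. A smaller set of 1778 contigs stood 8-fold or more above the others and made up 4.08% of that library's counts, against 0.4% in the noncleft palate.

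That cleft palate library 1 stands apart was weighed against 3 explanations. Sequencing depth is argued against, since at equal depth its mean Spearman correlation with the others was 0.548, while the lowest of the other libraries was 0.755. Contig length bias is argued against as the whole cause: 12.4% of contigs lay over 4-fold from the median of the other libraries, 11.4% after the length trend was removed, and at most 1.54% in any other library. A candidate explanation is a tissue part that made up less of this sample, since the 8269 low contigs also moved together across the other 5 libraries, with an SD of their medians of 0.134 against at most 0.019 in 1000 random sets matched on abundance and length. The 1778 high contigs passed the same test, at 0.086 against at most 0.073, so it does not single out a part that was lower, and any co-regulated set, the degree of the cleft and a wrong label stay open.

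The median log2 fold change of contigs of 300 nt up to the next class at 500 nt exceeded that of contigs of 2000 nt or longer by 0.338 in the cleft palate. This gap may come from cleft palate library 1 alone, but the test left that open: without that library it was 0.105, and with each of the other libraries left out in turn it was 0.316 to 0.551. Fragment length, which was shortest in cleft palate libraries 1 and 2, was not tested as an explanation and stays open.

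The contigs absent from the cleft palate could reflect reads divided differently between contigs of one family, such as isoforms or alleles that differ between fish. Of the 7 families with more than 1 contig, 4 differed by under 2-fold between groups once summed, with log2 ratios from -2.48 to 0.42 over the 7. For the other 3 and for the single-contig family, a lower level of the whole family stays open. As many contigs absent from one trio of libraries were found in 6 of the 10 splits, with 9 in the real split and 21 in the highest other. Summed per family, the real split gave 1, the single-contig family, and the others gave 0 to 3, with 1 or more in 8 of the other 9.

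The splits of the 6 libraries into 3 and 3 number only 10, the real one included, so no share under 0.05 can be reached. The real split gave 0 calls in edgeR, with or without a doubling or halving, so that 10 of 10 splits give as many is fixed and says nothing about chance; the highest other count was 0. The 3511 contigs with an unadjusted edgeR p under 0.05 were matched in 1 of 10 splits, the real one, with 2862 in the highest other. The 109 DESeq2 calls were matched in 1 of 10, with 78 in the highest other. The 758 calls of edgeR without the low-count filter were matched in 2 of 10, with 391 to 802 in the other splits.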
